A study of Mus musculus with 27 samples.

How the data were processed

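Bulk RNA sequencing of purified HSPCs was analysed in 27 libraries, 3 in each of 9 groups. Per the labels, total RNA was extracted with Tri Pure reagent and libraries were made with an Illumina TruSeq RNA kit. The submitters' processing notes name Trim Galore, FastQC, STAR 2.7 and HTSeq 0.6.1p1 and the GRCm38 build. Values were taken as deposited, as FPKM computed by the authors. The tool that computed FPKM, the annotation and any further scaling between libraries are not given in the sources used here. The table held 24418 entries with 24416 distinct symbols, of which 23528 were found in the reference tables used for positions. Date-like names (27 entries) were left unnamed.

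Every library had a single column, and each column was used. Because counts are not given, the depth is unknown. A relative depth was computed from the steps between the lowest values of each library, and the scale factors of a median-of-ratios scaling lay between 0.983 and 1.014. The 10 most abundant genes held 6 to 8.3% of the FPKM of a library. Libraries with the same replicate number were not more alike than others (residual correlations from -0.21 to 0.13, and 8 of 27 libraries closest to their own number), so replicates were treated as unpaired.

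FPKM were transformed to log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 3 libraries (13350 genes) were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with a mean for each of the 9 groups fitted to all 27 libraries, which left 18 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The 5 main comparisons were E12.5 FL with E12.5 PL, E16.5 FL with E12.5 FL, Perinatal BM with E16.5 FL, 8w BM with Perinatal BM and 8w BM with E16.5 FL, and the 5 steps were those between successive BM groups. Gene lists (34 lists with 792 members, of which 787 were matched and 730 tested) were written from general knowledge. They were tested with camera from limma, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 34 lists of a comparison. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 was used for depth and figures.

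The groups, the comparisons, the lists, the limma and camera tests and the rule for naming genes were chosen before the data were examined. In the main comparisons the rule named the 8 genes with the largest fold in each direction among those with an adjusted p under 0.05, a mean FPKM of at least 5 in the higher group and no overlap between the libraries of the groups, which chance gives for 10% of genes. Genes known only by a clone or predicted-gene number, pseudogenes and mitochondrial genes were not named. The steps named 3 genes in each direction. Lists were illustrated by up to 4 members with the smallest adjusted p, and any gene of the fetal HSC programme could be named. Some genes that the rule would name are not reported here. Library values of Cpa3, Prg2, Epx, Ms4a2, Cd74, Elane and Xist, and the levels of Ptprc, were chosen after their values were seen.

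The calling was tested on simulated data, drawn from the group means and the residual spread, with the compared groups given the same mean before changes were added to some genes with a mean of at least 5 FPKM. Each gene was drawn independently, with 1 spread for all groups. Recovery at lower levels, and the effect of a spread that differs between groups, were therefore not tested. At a log2 change of 0.5, 70.1% of changed genes were called in the design of E16.5 FL with E12.5 FL and 71.6% in that of 6w BM with 4w BM. At a log2 change of 1 the shares were 95.5% and 98.5%, and 7 unchanged genes were called in each. Alternatives were a pseudocount of 0.1, no filter, a filter at an FPKM of 5, a median-of-ratios scaling, a fit of only the 6 libraries compared, a block for the replicate number, and leaving out each library in turn. Chosen after seeing the data were a fit without the E12.5 PL libraries, the Y-linked level of each library as a covariate, and 1w BM in place of Perinatal BM or 6w BM in place of 8w BM. Where a left-out library leaves 2 in its group, the spread is pooled over the groups.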

Results

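Bulk RNA sequencing measured the transcriptome of purified haematopoietic stem and progenitor cells (HSPCs) of C57BL/6 mice in 9 groups that differ in age or source, with 3 libraries per group. The groups, named as in the labels, were E12.5 PL, E12.5 FL, E16.5 FL, Perinatal BM, and BM at 1, 3, 4, 6 and 8 weeks of age (1w to 8w BM). FL and BM are the field's usual abbreviations of fetal liver and bone marrow, and PL is not spelled out in the labels. The markers used for purification, the sex of the animals and the day of the perinatal collection are not given in the sources used here. Expression was given as FPKM, so the total count per library is unknown, and folds are on the log2(FPKM + 1) scale, which understates them at low levels. FPKM summed to 519810 to 763033 per library, and to at most 611034 outside E12.5 PL, and 14241 to 16964 genes had a value above 0. From the steps between low values, the depth of a library lay between 0.68 and 1.64 times that of the median library, with group means from 0.81 in 4w BM to 1.53 in E12.5 FL.

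Across genes, which are not independent replicates, libraries of the same group correlated at r = 0.979 to 0.995. Libraries of different groups correlated at 0.927 to 0.99 where E12.5 PL was left out, and E12.5 PL with any other group at 0.667 to 0.781. Principal component 1, with 67% of the variance, held E12.5 PL apart from the other 24 libraries, and component 2, with 12.2%, ran from E12.5 FL through E16.5 FL, Perinatal BM and 1w BM to the older BM groups. The numbers of changed genes were largest between E12.5 FL and E12.5 PL (9911 of 13350 genes tested), and 526 genes changed between 4w BM and 6w BM. The p-values measure only the spread between these libraries, and comparisons that share a group share its libraries.

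**Figure D1:**
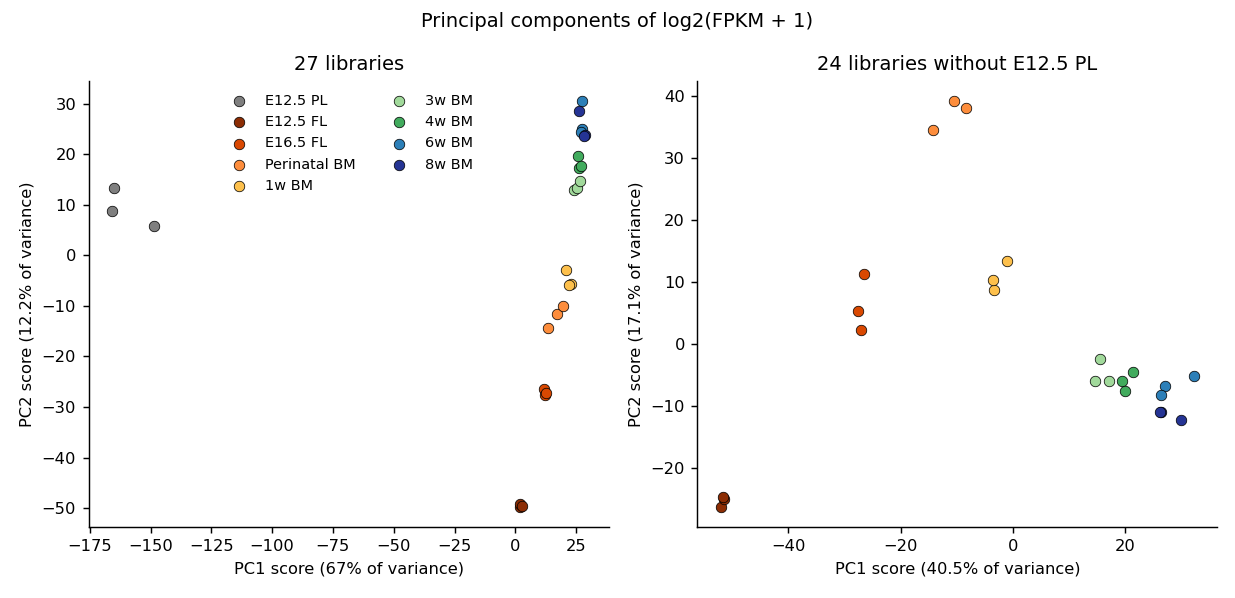
Scores of each library on the first and second principal components of log2(FPKM + 1), for 27 libraries (left) and for the 24 libraries without E12.5 PL (right). Each point is a library, coloured by group, and the 3 E12.5 PL libraries lie alone on the first component of the left plot.

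**Figure D2:**
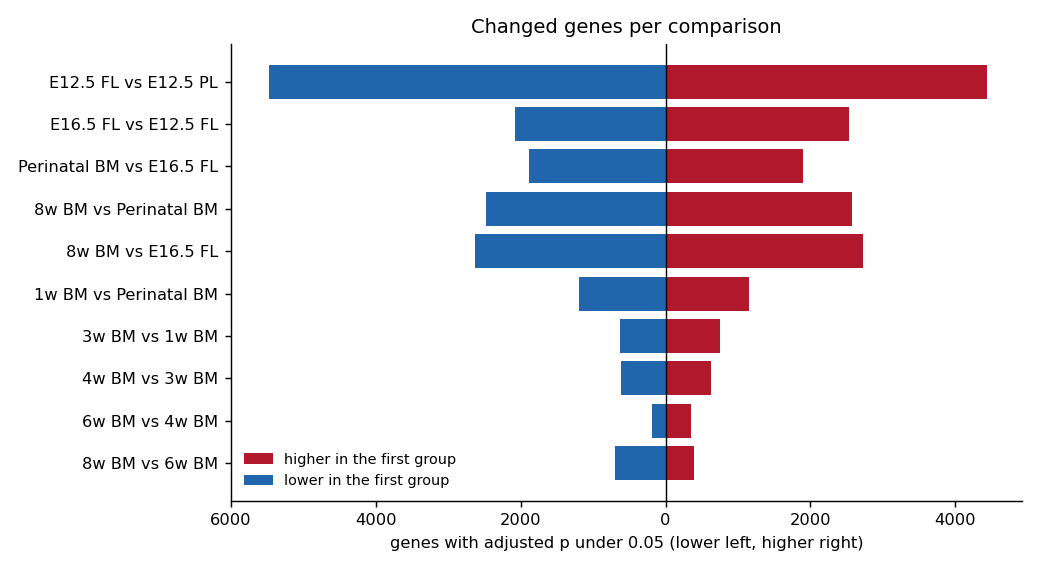
Number of genes that passed an adjusted p of 0.05 in limma in each of the 10 comparisons, higher (right) or lower (left) in the group named first. E12.5 FL against E12.5 PL gave 4432 higher and 5479 lower genes.

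The comparison of E12.5 FL with E12.5 PL asked how HSPCs of the same embryonic age differed between these sources. Flt3, a cytokine receptor of early progenitors, stood at 86 ± 3.59 FPKM (SD, n = 3) in FL and 7.02 ± 1.89 in PL, and Hlf, a transcription factor of stem cells, at 41.5 ± 0.558 and 2.59 ± 0.531. Cd48 and Cd27, surface proteins of haematopoietic cells, were 12.7-fold and 13.7-fold higher in FL on the log2(FPKM + 1) scale, and the chemokine genes Ccl3 and Ccl4 21.7-fold and 17.1-fold. The HSC identity list was not called (adjusted p = 0.294, and adjusted p = 0.922 with an estimated correlation). Of its 22 genes 12 rose and 7 fell (12 and 7 adjusted over the list alone), and Procr was at 4.14 ± 0.638 in FL against 148 ± 58.8 in PL. The HSC identity list shares 8 of its 22 genes with other lists. Tek and Robo4 are also in the endothelial list and Krt18 in the trophoblast list. Krt8, an epithelial keratin, stood at 872 ± 85.4 in PL and 0.457 ± 0.11 in FL, Sparc, a matrix glycoprotein, at 3840 ± 1440 and 1.93 ± 0.831, and Lamb1, a laminin chain of basement membranes, at 745 ± 279 and 0.165 ± 0.104. Sct, Cyr61, Hspb1, Pga5 and Gkn2 were the other genes with the largest falls from PL to FL, and Ifi203 and Nfe2 completed those with the largest rises.

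All 20 measured trophoblast genes were lower in FL than in PL, also when adjusted over the list alone (20 genes; camera, adjusted p = 6.18e-13, and adjusted p = 0.0102 with an estimated correlation). Only 2 of them reached a mean FPKM of 1 in FL, and 1 to 3 in each BM group. Most thus passed the filter through PL, which partly fixes their shared direction. Hand1, a trophoblast transcription factor, was listed at 0 in FL and at 159 ± 7.06 in PL, and Krt19 and Plac1 fell by 8.89 and 8.49 on the log2 scale. Of 23 imprinted genes, 22 were lower in FL and 1 higher, with the same counts adjusted over the list alone (adjusted p = 5.68e-11, and adjusted p = 0.00395 with an estimated correlation). Of the 23, 22 reached a mean FPKM of 1 in PL and 12 in FL, and 5 are in another list. Those below 1 in FL may have passed the filter through PL, which would partly fix their shared direction. Mest was at 0.681 ± 0.311 in FL and 407 ± 76.5 in PL, and Peg10, a gene needed for placental development, at 1.99 ± 0.272 and 487 ± 89.7. Of 22 endothelial genes, 21 fell and 1 rose (21 and 1 adjusted over the list alone), among them the junction gene Cdh5 (1.96 ± 0.142 against 242 ± 21.4) and Cldn5. Of 20 genes of stroma and mesenchyme, 19 fell (19 adjusted over the list alone), among them the basement membrane collagen Col4a1 (5.38 ± 0.429 against 3830 ± 1580) and Kitl, the ligand of the Kit receptor. The endothelial call had adjusted p = 2.88e-08, and adjusted p = 0.0655 with an estimated correlation. The stromal call had adjusted p = 1.44e-08, and adjusted p = 0.161 with an estimated correlation. Of 18 genes of heat shock and stress, 15 fell and none rose (15 adjusted over the list alone; adjusted p = 0.001, and adjusted p = 0.321 with an estimated correlation).

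Of 34 haematopoietic transcription factors, 27 rose from PL to FL and 6 fell (27 and 6 adjusted over the list alone; adjusted p = 7.02e-07, and adjusted p = 0.23 with an estimated correlation). Bcl11a stood at 72 ± 3.43 in FL and 5.74 ± 1.08 in PL, Myb at 144 ± 6.38 and 17.6 ± 3.72, and Lmo2 at 176 ± 3.6 and 24.2 ± 5.7. Of 24 genes of lymphoid priming and the B lineage, 13 rose and 2 fell (13 and 1 adjusted over the list alone), including Cd79b, a chain of the B cell receptor complex. That call had adjusted p = 0.00106, and adjusted p = 0.655 with an estimated correlation. Of 32 mitosis genes 25 rose and 3 fell, and of 30 DNA replication genes 22 rose and 4 fell, with the same counts adjusted over each list alone. Their calls had adjusted p = 0.000285 and 0.000614, and adjusted p = 0.577 for each with an estimated correlation. Top2a was at 166 ± 9.29 in FL and 65 ± 8.46 in PL, and Mcm6, part of the replicative helicase, at 217 ± 5.75 and 101 ± 10.2. Of 17 DNA methylation genes 12 rose and 3 fell (12 and 3 adjusted over the list alone; adjusted p = 0.00252, and adjusted p = 0.0655 with an estimated correlation), led by the methyltransferase Dnmt3b at 155 ± 10.1 and 20.2 ± 4.88. In the fetal HSC programme, 6 of 13 genes rose and 4 fell, and the list as a whole was not called (adjusted p = 0.279). Hmga2 and Lin28b rose 8.69-fold and 7.66-fold, while Sox17, a transcription factor of fetal stem cells and endothelium, was at 0.364 ± 0.172 in FL and 38 ± 10.8 in PL. In limma, 4432 genes were higher in FL and 5479 lower, 1241 and 3006 of them by at least 2-fold. Ptprc, the gene of the leukocyte antigen CD45, was at 65.3 in FL and 7.91 in PL. All 20 pan-leukocyte genes, a set chosen after the results were seen, were lower in PL, by 5.62-fold in the median. Cells of other types in PL could thus lower the transcription factor, lymphoid and fetal genes there. That was not told apart from a difference in the HSPCs themselves.

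The comparison of E16.5 FL with E12.5 FL followed HSPCs within the same source. S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, stood at 243 ± 123 and 102 ± 52.2 FPKM (SD, n = 3) at E16.5 and at 1.62 ± 0.926 and 0.237 ± 0.411 at E12.5. Elane, the neutrophil elastase, rose from 2.54 ± 0.792 to 109 ± 70.8, and the granule genes Ngp and Camp from values listed at 0 to 23.8 ± 10 and 22.3 ± 7.37. Igll1 and Vpreb3, parts of the surrogate light chain or its assembly in B cell precursors, rose by 4.85 and 4.32 on the log2 scale. Mdk, a heparin-binding growth factor, fell from 20.5 ± 0.791 to 1.63 ± 0.595, the imprinted growth factor Igf2 from 41.9 ± 1.89 to 9.43 ± 2.49, and Igf2bp1, an RNA-binding protein of the fetal programme, from 29.9 ± 1.51 to 8.38 ± 2.36. The falls of Eno1b, Perp, Cdh17 and Zfp711 were between 3.66-fold and 4.78-fold.

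Of 24 lymphoid genes, 17 rose and 1 fell (17 and 2 adjusted over the list alone). Ebf1, a B lineage transcription factor, was at 9.5 ± 4.49 against 0.34 ± 0.0988. Of 19 neutrophil genes, 11 rose and 4 fell (12 and 4 adjusted over the list alone). The lymphoid call had adjusted p = 5.12e-07, and adjusted p = 0.275 with an estimated correlation, and the neutrophil call adjusted p = 0.00013, and adjusted p = 0.395 with an estimated correlation. Of 20 erythroid genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 5.12e-07, and adjusted p = 0.211 with an estimated correlation), among them Hemgn (8.38 ± 0.856 against 3.18 ± 0.648). Of 16 monocyte and macrophage genes, 9 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.00013, and adjusted p = 0.211 with an estimated correlation). The macrophage gene Mpeg1 was at 7.75 ± 1.22 against 1.71 ± 0.196 and C1qc at 3.7 ± 0.895 against 0.253 ± 0.216. Of 32 interferon response genes, 23 rose and none fell (24 adjusted over the list alone), and of 15 MHC class I genes, 12 rose and none fell (13 adjusted over the list alone). H2-K1, which presents peptides to CD8 T cells, went from 75.4 ± 3.85 to 138 ± 6.25, the peptide transporter Tap1 from 15.3 ± 0.217 to 26.7 ± 2.05, and the interferon-induced Ifitm3 from 101 ± 10.3 to 205 ± 28.8. These calls had adjusted p = 9.02e-08 for the interferon response and 5.12e-07 for MHC class I, and adjusted p = 0.275 and 0.211 with an estimated correlation. Of 9 MHC class II genes, 8 rose (9 adjusted over the list alone; adjusted p = 2.25e-06, and adjusted p = 0.211 with an estimated correlation). H2-DMa was at 22.5 ± 2.65 against 8.74 ± 1.68.

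Of 30 DNA replication genes 21 fell and none rose, and of 32 mitosis genes 15 fell and none rose, with the same counts adjusted over each list alone. Fen1, a flap endonuclease of DNA replication, went from 60.5 ± 5.22 to 37.7 ± 2.37, and Aurka, a mitotic kinase, from 56.3 ± 1.86 to 31.9 ± 3.24. These calls had adjusted p = 1.34e-06 and 2.2e-05, and adjusted p = 0.275 and 0.336 with an estimated correlation. Of 23 genes of CDK inhibitors and quiescence 16 rose and none fell (16 adjusted over the list alone; adjusted p = 3.64e-07, and adjusted p = 0.211 with an estimated correlation). That list shares Egr1, Btg2, Klf4 and Klf6 with the immediate-early list, and 8 of its 23 genes are in another list. Txnip was at 203 ± 26.3 against 67.8 ± 6.75. Of 22 HSC identity genes 12 rose and none fell (12 adjusted over the list alone; adjusted p = 5.93e-05, and adjusted p = 0.275 with an estimated correlation). Procr, the endothelial protein C receptor used as an HSC marker, rose from 4.14 ± 0.638 to 16.3 ± 2.28, and Mecom, a regulator of HSC maintenance, from 5.36 ± 0.0639 to 14.6 ± 1.6. Of 13 genes of the fetal HSC programme 7 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.00189, and adjusted p = 0.211 with an estimated correlation), with Lin28b, which blocks the maturation of let-7, falling from 31.5 ± 1.38 to 13 ± 1.65. Of 28 oxidative phosphorylation genes 14 fell and none rose (18 adjusted over the list alone; adjusted p = 2.2e-06, and adjusted p = 0.41 with an estimated correlation), among them Cycs, the cytochrome c of the respiratory chain. Of 22 immediate-early genes 13 rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 7e-04, and adjusted p = 0.515 with an estimated correlation), with Fosb rising from 12.3 ± 4.98 to 87 ± 15.3 and Myc falling from 106 ± 5.09 to 62.6 ± 3.91. Of 23 glycolysis genes 10 fell and 5 rose (10 and 5 adjusted over the list alone; adjusted p = 0.0178, and adjusted p = 0.275 with an estimated correlation), among them Pgk1 and Aldoa, which fell by 0.80 and 0.72 on the log2 scale. In limma, 2539 genes were higher at E16.5 and 2081 lower, 413 and 92 of them by at least 2-fold. No list call of this comparison held with an estimated correlation.

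The comparison of Perinatal BM with E16.5 FL spanned the move of haematopoiesis from liver to marrow around birth. Mast cell genes showed most of the largest rises. Rps27 also rose, 74.7-fold on the log2(FPKM + 1) scale, while its near-identical copy Rps27rt fell 8.62-fold, so each value alone is uncertain. The proteases Cma1, Tpsb2, Mcpt4 and Cpa3 stood at 773 ± 386, 849 ± 349, 255 ± 117 and 623 ± 282 FPKM (SD, n = 3) in Perinatal BM, and at 5.35 ± 5.25, 7.96 ± 9.11, 1.63 ± 1.59 and 9.04 ± 5.78 in E16.5 FL. Gzmb, a granule protease, Hdc, which makes histamine, and Il1rl1, the receptor of IL-33, rose 42-fold, 35.4-fold and 26.6-fold on the log2(FPKM + 1) scale. Vpreb1, a gene of B cell precursors, fell from 23.8 ± 14.8 to 2.28 ± 2.32 and the imprinted RNA H19 from 84.1 ± 1.95 to 15.7 ± 14.2. The histone gene Hist1h2bb and the B cell coactivator Pou2af1 fell 5.77-fold and 5.3-fold.

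All 16 measured genes of the mast cell and basophil list rose (16 adjusted over the list alone; adjusted p = 9.42e-27, and adjusted p = 0.000971 with an estimated correlation). Cpa3 was at 716, 306 and 846 in Perinatal BM libraries 1, 2 and 3, while Prg2 (160, 131 and 26.5), Epx (10.3, 10.2 and 1.67) and Ms4a2 (6.32, 5.04 and 3.85) were lowest in library 3. The genes of the list thus did not vary as one between these libraries, and whether all come from mast cells or basophils was not tested. Of 9 MHC class II genes 8 rose (9 adjusted over the list alone; adjusted p = 6.44e-07, and adjusted p = 0.179 with an estimated correlation), and their level differed between the libraries, with Cd74, the invariant chain, at 34.9, 61.6 and 181. Of 15 MHC class I genes 10 rose and none fell (11 adjusted over the list alone; adjusted p = 6.44e-07, and adjusted p = 0.106 with an estimated correlation), with H2-K1 going from 138 ± 6.25 to 255 ± 0.593 and H2-D1 from 115 ± 4.91 to 221 ± 22.5. Of 32 mitosis genes 27 fell and none rose (28 adjusted over the list alone; adjusted p = 1.96e-15, and adjusted p = 0.106 with an estimated correlation). Hmmr, a spindle protein, was at 9.81 ± 0.628 against 22.4 ± 2.06 and the mitotic kinase Plk1 at 19.4 ± 2.8 against 36.2 ± 3.34. Of 18 genes of heat shock and stress 11 fell and none rose (14 adjusted over the list alone; adjusted p = 6.44e-07, and adjusted p = 0.106 with an estimated correlation). Hspa5, the chaperone BiP of the endoplasmic reticulum, was at 300 ± 25 against 718 ± 150. Of 23 imprinted genes 10 fell and none rose (10 adjusted over the list alone; adjusted p = 0.000481, and adjusted p = 0.106 with an estimated correlation). The cell cycle inhibitor Cdkn1c was at 6.3 ± 1.77 against 16.1 ± 0.34.

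Of 24 lymphoid genes 13 fell and 2 rose (15 and 2 adjusted over the list alone; adjusted p = 0.000571, and adjusted p = 0.512 with an estimated correlation). Dntt, the terminal transferase of lymphoid progenitors, rose to 2.67 ± 0.704 from 0.377 ± 0.18. Of 20 erythroid genes 9 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 0.000571, and adjusted p = 0.422 with an estimated correlation), with the band 3 gene Slc4a1 falling to 0.0366 ± 0.0453 from 2.56 ± 0.891. Of 22 HSC identity genes 11 fell and 2 rose (14 and 5 adjusted over the list alone; adjusted p = 0.00319, and adjusted p = 0.509 with an estimated correlation). Mycn was at 20.8 ± 2.77 against 76 ± 5.76 and Gata2, also active in mast cells, at 94.7 ± 4.97 against 39.3 ± 2.81. Of 22 endothelial genes 8 fell (8 fell and 1 rose adjusted over the list alone; adjusted p = 0.0174, and adjusted p = 0.486 with an estimated correlation). Of 13 genes of the fetal HSC programme 4 fell and 2 rose, with the same counts adjusted over the list alone (adjusted p = 0.0256, and adjusted p = 0.242 with an estimated correlation). Igf2bp1 fell from 8.38 ± 2.36 to 0.928 ± 0.0867 and Igf2bp2 from 38.8 ± 2.95 to 19.6 ± 1.34. Without Perinatal BM 3 the call of the fetal programme was lost (adjusted p = 0.17). So were those of the immediate-early genes (7 of 22 rose and 1 fell, the same adjusted over the list alone; adjusted p = 0.0197, 0.697 with an estimated correlation and 0.0802 without that library) and of the interferon response (8 of 32 rose, the same adjusted over the list alone; adjusted p = 0.000485, 0.531 with an estimated correlation and 0.227 without that library). In limma, 1896 genes were higher in Perinatal BM and 1890 lower, 297 and 143 of them by at least 2-fold. With only the 6 libraries compared in the fit 2145 genes passed, and the calls of Vpreb1, Pou2af1 and the lymphoid list (adjusted p = 0.0597) were lost. With the filter at an FPKM of 5 the calls of the lymphoid list (adjusted p = 0.0575) and of the erythroid list (0.109) were lost.

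The comparison of 8w BM with Perinatal BM covered the whole of postnatal growth in marrow. Igf2bp3, an RNA-binding protein of fetal cells encoded on chromosome 6 (49085218 to 49215469, GRCm38), fell from 47.5 ± 1.73 to 0.74 ± 0.3 FPKM (SD, n = 3). Hmga2, a chromatin protein that promotes self-renewal of fetal stem cells, fell from 115 ± 5.9 to 9.15 ± 1.39, and Lin28b from 10.2 ± 0.764 to 0.0422 ± 0.04. Dntt rose from 2.67 ± 0.704 to 145 ± 31.3, and the complement genes C1qa, C1qb and C1qc, expressed by macrophages, rose from 0.397 ± 0.225 or less to 21.8 ± 6.99, 23.8 ± 8.89 and 22.8 ± 7.67. Fcna, a lectin of macrophages, rose from 0.0268 ± 0.0464 to 17.2 ± 6.24. The class I genes H2-Q7, H2-Q8 and H2-Q9 rose from 0.894 ± 0.415 or less to 86.9 ± 13.9, 84 ± 12 and 20 ± 3.98, values that are uncertain since reads of these near-identical copies can be split between them. Tpsb2 fell by 9.21 on the log2 scale and Cma1 fell by 8.54. Stfa1, a stefin of myeloid cells, was listed at 0 in 8w BM and at 194 ± 124 in Perinatal BM, and S100a8 fell from 263 ± 175 to 6.52 ± 2.83.

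**Figure D3:**
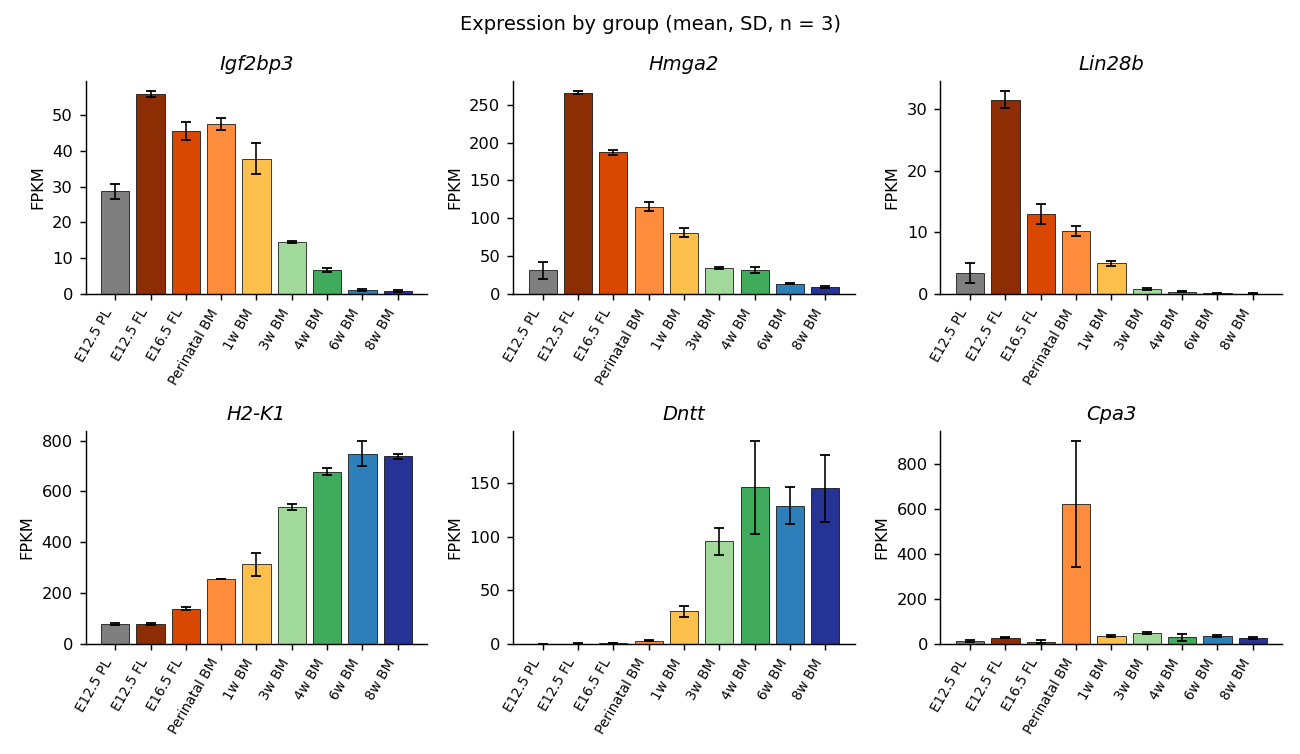
Mean FPKM of 6 genes in the 9 groups, with bars starting at 0 and error bars of 1 SD (n = 3). Igf2bp3, Hmga2 and Lin28b were lowest in 8w BM, H2-K1 was at 75.4 in E12.5 FL and 738 in 8w BM, and Cpa3 stood at 623 in Perinatal BM.

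Of 13 genes of the fetal HSC programme 8 fell and none rose (9 adjusted over the list alone; adjusted p = 3.78e-09, and adjusted p = 0.00464 with an estimated correlation). Among those that fell, Lin28a (0.67 to 0.0223) and Igf2bp1 (0.928 to 0.0121) were below a mean FPKM of 1 in both groups. Of 15 MHC class I genes 14 rose and none fell (14 adjusted over the list alone; adjusted p = 2.8e-12, and adjusted p = 0.0189 with an estimated correlation). H2-K1 was at 738 ± 8.56 against 255 ± 0.593 and Nlrc5, the transactivator of class I genes, at 13.7 ± 1.16 against 2.28 ± 0.511. Of 16 genes of the mast cell and basophil list 13 fell (14 adjusted over the list alone; adjusted p = 8.75e-15, and adjusted p = 0.0109 with an estimated correlation). Of 23 imprinted genes 12 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 3.45e-05, and adjusted p = 0.0442 with an estimated correlation), with the Notch-family ligand Dlk1 falling from 14.5 ± 0.426 to 0.336 ± 0.118. Of 16 monocyte and macrophage genes 13 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 5.97e-07, and adjusted p = 0.0555 with an estimated correlation), including Mrc1, the mannose receptor. Of 32 interferon response genes 15 rose and none fell (15 adjusted over the list alone; adjusted p = 7.98e-06, and adjusted p = 0.619 with an estimated correlation). Irgm1 was at 27.1 ± 0.942 against 13.8 ± 2.24. Of 20 erythroid genes 12 rose and none fell (12 adjusted over the list alone; adjusted p = 0.00022, and adjusted p = 0.434 with an estimated correlation). Car1, a carbonic anhydrase, was at 145 ± 63.1 against 15.5 ± 7.47. Of 32 mitosis genes 13 rose and 2 fell (13 and 3 adjusted over the list alone; adjusted p = 0.0372, and adjusted p = 0.831 with an estimated correlation). That call was lost without Perinatal BM 1 (adjusted p = 0.125), Perinatal BM 2 (0.05), 8w BM 1 (0.271) or 8w BM 2 (0.0716), without E12.5 PL (0.0554) and with the Y-linked covariate (0.0671). Of 23 glycolysis genes 11 fell and 3 rose (12 and 3 adjusted over the list alone; adjusted p = 0.0292, 0.389 with an estimated correlation and 0.057 without Perinatal BM 3), among them the glucose transporter Slc2a1 at 13.2 ± 1.75 against 34.3 ± 2.37.

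In limma, 2568 genes were higher in 8w BM and 2482 lower, 328 and 436 of them by at least 2-fold. The Y-linked genes Ddx3y and Eif2s3y stood at 24.8 ± 7.16 and 31.8 ± 8.67 in Perinatal BM and at 0.049 ± 0.0186 and 0.119 ± 0.0326 in 8w BM, so the groups also differed in Y-linked expression. With the Y-linked level of each library as a covariate, an alternative chosen after the data were seen, 2921 genes passed and the standard errors rose 1.6-fold in the median. With 1w BM in place of Perinatal BM, likewise chosen after the data were seen, 2490 genes passed, 1879 of them shared in the same direction.

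The comparison of 8w BM with E16.5 FL set the oldest group against the last fetal liver group. Dntt rose from 0.377 ± 0.18 to 145 ± 31.3 FPKM (SD, n = 3), Car1 from 2.16 ± 0.941 to 145 ± 63.1, Cpne2, a calcium-dependent membrane-binding protein, from 1.62 ± 0.522 to 52 ± 2.63, and Pf4, the platelet factor of megakaryocytes, from 3.78 ± 1.27 to 71 ± 5.24. H19 fell from 84.1 ± 1.95 to 0.287 ± 0.18, S100a9 from 102 ± 52.2 to 2.7 ± 0.344 and Igll1 from 35.7 ± 20.9 to 0.222 ± 0.259. Of 13 genes of the fetal HSC programme 10 fell and none rose (10 adjusted over the list alone; adjusted p = 2.47e-10, and adjusted p = 0.00234 with an estimated correlation). Among those that fell, Sox17 (0.33 to 0.024) and Lin28a (0.371 to 0.0223) were below an FPKM of 1 in both groups. Igf2bp2 went from 38.8 ± 2.95 to 1.42 ± 0.434 and Hmga2 from 187 ± 3.09 to 9.15 ± 1.39. All 15 MHC class I genes rose (15 adjusted over the list alone; adjusted p = 6.02e-16, and adjusted p = 0.00801 with an estimated correlation), H2-K1 by 5.31-fold and H2-D1 by 4.84-fold. Of 23 imprinted genes 14 fell and 2 rose (14 and 2 adjusted over the list alone; adjusted p = 2.19e-07, and adjusted p = 0.0115 with an estimated correlation). Ndn was at 2.71 ± 0.318 against 15.6 ± 2.63.

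Of 32 interferon response genes 27 rose and none fell (28 adjusted over the list alone; adjusted p = 4.82e-11, and adjusted p = 0.217 with an estimated correlation). Ifi44 was at 10.7 ± 0.846 against 1.18 ± 0.638. All 9 MHC class II genes rose (9 adjusted over the list alone; adjusted p = 3.64e-06, and adjusted p = 0.217 with an estimated correlation). Of 16 monocyte and macrophage genes 13 rose (13 adjusted over the list alone; adjusted p = 1.24e-06, and adjusted p = 0.0996 with an estimated correlation). Vcam1 was at 14.3 ± 5.02 against 0.833 ± 0.493. Of 19 megakaryocyte genes 12 rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 0.000249, and adjusted p = 0.289 with an estimated correlation). The integrin Itga2b was at 58.3 ± 4.93 against 7.53 ± 1.14 and the platelet glycoprotein Gp5 at 10.6 ± 2.28 against 0.705 ± 0.182. Of 24 lymphoid genes 15 fell and 3 rose (15 and 3 adjusted over the list alone; adjusted p = 7.36e-06, and adjusted p = 0.314 with an estimated correlation), with the homing receptor Ccr9 falling from 10.2 ± 0.497 to 0.571 ± 0.367. Of 22 HSC identity genes 14 fell and 3 rose (14 and 3 adjusted over the list alone; adjusted p = 0.000596, and adjusted p = 0.361 with an estimated correlation). Fgd5, an HSC marker, was at 2.07 ± 0.455 against 17 ± 3.06. Of 32 mitosis genes 22 fell and none rose (22 adjusted over the list alone; adjusted p = 2.52e-06, and adjusted p = 0.289 with an estimated correlation). Cenpa, the centromeric histone, was at 67.5 ± 4.86 against 117 ± 3.56. In limma, 2732 genes were higher in 8w BM and 2630 lower, 484 and 455 of them by at least 2-fold. Ddx3y was at 24.1 ± 7.83 in E16.5 FL and 0.049 ± 0.0186 in 8w BM.

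Between Perinatal BM and 1w BM, Tpsb2 went from 849 ± 349 to 19 ± 6.23 FPKM (SD, n = 3), Cpa3 fell 17.4-fold, and Dntt rose from 2.67 ± 0.704 to 30.1 ± 4.86. Of 16 genes of the mast cell and basophil list 13 fell and none rose (13 adjusted over the list alone; adjusted p = 2.26e-18, and adjusted p = 0.00765 with an estimated correlation). Plk1 rose from 19.4 ± 2.8 to 36.3 ± 2.69 and Tpx2, a spindle assembly factor, from 25.7 ± 1.55 to 40.5 ± 0.763. Of 32 mitosis genes 26 rose and none fell (29 adjusted over the list alone; adjusted p = 2.29e-18, and adjusted p = 0.0961 with an estimated correlation). Of 30 DNA replication genes 12 rose and none fell (14 adjusted over the list alone; adjusted p = 3.63e-07, and adjusted p = 0.355 with an estimated correlation). In the fetal HSC programme 7 of 13 genes fell and none rose (8 adjusted over the list alone; adjusted p = 8e-04, and adjusted p = 0.0961 with an estimated correlation), Igf2bp2 going from 19.6 ± 1.34 to 9.49 ± 0.655 and Lin28b from 10.2 ± 0.764 to 4.95 ± 0.422. Of 22 immediate-early genes 10 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.000385, and adjusted p = 0.689 with an estimated correlation). The nuclear receptor Nr4a2 was at 11.4 ± 4.89 against 39.8 ± 4.42. Of 28 adhesion and homing genes 8 fell and 2 rose (9 and 2 adjusted over the list alone; adjusted p = 0.0095, and adjusted p = 0.188 with an estimated correlation). The integrin Itga9 was at 4.64 ± 0.377 against 9.69 ± 2.02. Of 9 MHC class II genes 5 fell (6 adjusted over the list alone; adjusted p = 0.0201, 0.689 with an estimated correlation, 0.252 without Perinatal BM 3 and 0.0581 with only the 6 libraries compared in the fit). In limma, 1148 genes were higher in 1w BM and 1197 lower, 59 and 192 of them by at least 2-fold. The total of 2345 fell to 1531 without 1w BM 1 and to 1462 without 1w BM 3, and 899 genes passed with only the 6 libraries compared in the fit.

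Between 1w BM and 3w BM, Stfa1 and S100a9 went from 140 ± 31.1 and 139 ± 34.2 to 0.206 ± 0.357 and 6.43 ± 1.26 FPKM (SD, n = 3). Of 19 neutrophil genes 7 fell and none rose (9 fell and 1 rose adjusted over the list alone; adjusted p = 2.69e-06, and adjusted p = 0.255 with an estimated correlation). Klf2, a transcription factor of quiescence, rose from 15.3 ± 2.67 to 254 ± 88.6, the stress factor Atf3 from 6.17 ± 2.06 to 58.5 ± 2.58, and the chemokine gene Ccl4 from 13.6 ± 3.53 to 125 ± 12.6. In the fetal HSC programme 9 of 13 genes fell and none rose (9 adjusted over the list alone; adjusted p = 1.74e-11, and adjusted p = 0.00126 with an estimated correlation), with Igf2bp3 going from 37.9 ± 4.39 to 14.5 ± 0.302 and Lin28b from 4.95 ± 0.422 to 0.801 ± 0.166. Of 23 imprinted genes 8 fell (8 adjusted over the list alone; adjusted p = 2.45e-05, and adjusted p = 0.0434 with an estimated correlation). The adaptor protein gene Grb10 was at 7.84 ± 0.585 against 17.6 ± 0.553. Of 18 genes of heat shock and stress 10 rose (11 adjusted over the list alone; adjusted p = 1.25e-09, and adjusted p = 0.0367 with an estimated correlation). The chaperone Hsph1 was at 49.1 ± 6.44 against 19.6 ± 0.251. Of 15 MHC class I genes 8 rose (10 adjusted over the list alone; adjusted p = 8.92e-11, and adjusted p = 0.0367 with an estimated correlation), H2-K1 going from 312 ± 45.4 to 538 ± 11.7. Of 22 immediate-early genes 16 rose (19 adjusted over the list alone; adjusted p = 3.65e-16, and adjusted p = 0.124 with an estimated correlation). Jun was at 1140 ± 202 against 351 ± 54.9. Of 32 interferon response genes 18 rose (27 adjusted over the list alone; adjusted p = 3.37e-15, and adjusted p = 0.124 with an estimated correlation). Irf9 was at 32.8 ± 2.74 against 20.1 ± 1.49. Of 16 genes of the mast cell and basophil list 8 fell (8 adjusted over the list alone; adjusted p = 6.06e-06, and adjusted p = 0.124 with an estimated correlation), and of 16 monocyte and macrophage genes 7 rose (8 adjusted over the list alone; adjusted p = 4.14e-05, and adjusted p = 0.128 with an estimated correlation). Of 22 HSC identity genes 8 fell (11 fell and 1 rose adjusted over the list alone; adjusted p = 5.05e-05, and adjusted p = 0.255 with an estimated correlation). Fgd5 was at 2.09 ± 0.205 against 6.47 ± 1.56. In limma, 759 genes were higher in 3w BM and 635 lower, 124 and 65 of them by at least 2-fold. The total of 1394 fell to 738, 908, 768, 882 and 907 without 1w BM 1, 1w BM 3, 3w BM 1, 3w BM 2 and 3w BM 3.

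Between 3w BM and 4w BM, S100a8 went from 27.3 ± 4.82 to 3.76 ± 1.04 FPKM (SD, n = 3) and Igll1 from 5.48 ± 0.824 to 0.232 ± 0.267, while Lag3, an inhibitory receptor, rose from 4.47 ± 1.3 to 11 ± 0.338. Of 19 neutrophil genes 10 fell and 2 rose (10 and 2 adjusted over the list alone; adjusted p = 6.92e-06, and adjusted p = 0.52 with an estimated correlation). Elane was at 53.5, 391 and 65.8 in 4w BM libraries 1, 2 and 3 and at 493 ± 20.6 in 3w BM, and its call (adjusted p = 0.018) was lost without 3w BM 1 (0.0713), 4w BM 1 (0.119) or 4w BM 3 (0.104). Of 18 genes of heat shock and stress 8 fell (13 adjusted over the list alone; adjusted p = 9.42e-08, and adjusted p = 0.208 with an estimated correlation). Hspa5 was at 350 ± 45.5 against 679 ± 19.2. Of 30 DNA replication genes 10 fell (16 adjusted over the list alone; adjusted p = 3.65e-10, and adjusted p = 0.289 with an estimated correlation). The licensing factor Cdt1 was at 57.3 ± 3.5 against 75.2 ± 1.33, and of 32 mitosis genes 8 fell (12 adjusted over the list alone; adjusted p = 4.15e-06, and adjusted p = 0.52 with an estimated correlation). Of 22 HSC identity genes 6 rose (12 adjusted over the list alone; adjusted p = 2.02e-06, and adjusted p = 0.404 with an estimated correlation). Pdzk1ip1 was at 16.1 ± 1.52 against 8.31 ± 1.51 and Esam at 11.1 ± 3.58 against 5.47 ± 1.17. Of 16 genes of the Hoxa and Hoxb clusters 6 rose (7 adjusted over the list alone; adjusted p = 0.000186, and adjusted p = 0.289 with an estimated correlation). Of 15 MHC class I genes 2 rose (4 adjusted over the list alone; adjusted p = 0.00132, and adjusted p = 0.52 with an estimated correlation). H2-K1 was at 678 ± 12.6 against 538 ± 11.7. In the fetal HSC programme, which was not called (adjusted p = 0.205), Igf2bp3 fell from 14.5 ± 0.302 to 6.62 ± 0.596. In limma, 630 genes were higher in 4w BM and 609 lower, 16 and 63 of them by at least 2-fold. The total of 1239 fell to 363, 698, 383 and 453 without 3w BM 1, 3w BM 3, 4w BM 1 and 4w BM 3, and 104 genes passed with only the 6 libraries compared in the fit, which ended the calls of Lag3, Elane, Cdt1, Pdzk1ip1 and Esam.

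Between 4w BM and 6w BM, Fosb went from 261 ± 36.5 to 1160 ± 417 FPKM (SD, n = 3), Egr1 from 552 ± 69.7 to 1470 ± 347, and the chaperone genes Hspa1a and Hspa1b from 0.695 ± 0.146 and 0.75 ± 0.286 to 14.3 ± 8.31 and 17.1 ± 11.8. Nlrp3, an inflammasome sensor, rose from 1.64 ± 1.21 to 14.1 ± 5.91. Igf2bp3 fell from 6.62 ± 0.596 to 1.05 ± 0.222 and Hmga2 from 30.9 ± 3.96 to 13.7 ± 0.226. Of 22 immediate-early genes 7 rose (17 adjusted over the list alone; adjusted p = 2.34e-13, and adjusted p = 0.359 with an estimated correlation). Of 18 genes of heat shock and stress 6 rose (9 adjusted over the list alone; adjusted p = 8.07e-09, and adjusted p = 0.0654 with an estimated correlation). Hspa5 was at 703 ± 111 against 350 ± 45.5. In the fetal HSC programme 2 of 13 genes fell (3 adjusted over the list alone; adjusted p = 0.000137, and adjusted p = 0.0654 with an estimated correlation). In limma, 346 genes were higher in 6w BM and 180 lower, 61 and 15 of them by at least 2-fold. The total of 526 fell to 277, 262 and 237 without 4w BM 1, 4w BM 3 and 6w BM 2. With only the 6 libraries compared in the fit 10 genes passed, and of the genes named here only Igf2bp3 kept its call, with Fosb at adjusted p = 0.11 and Hspa1a at 0.14.

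Between 6w BM and 8w BM, the genes with the largest change were those of the sex chromosomes. Ddx3y and Eif2s3y, encoded on the Y chromosome, went from 43.6 ± 2.8 and 39.4 ± 11.3 to 0.049 ± 0.0186 and 0.119 ± 0.0326 FPKM (SD, n = 3), and Xist, the RNA of the inactive X chromosome, from 1.3 ± 1.45 to 194 ± 2.98. In the other groups Xist was at 0.371 in 4w BM 3, and between 12.3 and 110 in the remaining libraries. The list of Y-linked genes and Xist was called (4 of 5 fell and 1 rose, the same adjusted over the list alone; adjusted p = 7.65e-10, and adjusted p = 0.00775 with an estimated correlation). Of 22 immediate-early genes 19 fell and 1 rose (19 and 1 adjusted over the list alone; adjusted p = 8.1e-18, and adjusted p = 0.127 with an estimated correlation). Junb was at 403 ± 135 against 954 ± 238 and Nr4a1 at 390 ± 207 against 1200 ± 358. The chemokine gene Cxcl2 fell from 110 ± 52.4 to 13.2 ± 13.1. Of 18 genes of heat shock and stress 8 fell (10 adjusted over the list alone; adjusted p = 2.44e-08, and adjusted p = 0.0612 with an estimated correlation). Atf4 was at 194 ± 50.3 against 415 ± 36.6. Of 16 monocyte and macrophage genes 10 rose and none fell (11 adjusted over the list alone; adjusted p = 3.45e-11, and adjusted p = 0.0239 with an estimated correlation). C1qa was at 21.8 ± 6.99 against 5.62 ± 1.66 and Mpeg1 at 30.8 ± 3.74 against 13.2 ± 2.54, and Fcna rose from 3.44 ± 1.17 to 17.2 ± 6.24. Myl10, a myosin light chain, rose from 6.19 ± 0.748 to 44 ± 30.8. Of 23 genes of CDK inhibitors and quiescence 8 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.000561, and adjusted p = 0.313 with an estimated correlation). That list shares Egr1, Btg2, Klf4 and Klf6 with the immediate-early list, and 8 of its 23 genes are in another list. The p53 target Cdkn1a was at 54 ± 22.1 against 177 ± 60.8. In limma, 396 genes were higher in 8w BM and 696 lower, 29 and 167 of them by at least 2-fold. The total of 1092 fell to 478, 669 and 623 without 6w BM 2, 8w BM 1 and 8w BM 2, and to 6 with only the 6 libraries compared in the fit, where the named genes other than Ddx3y, Eif2s3y and Xist lost their calls. With the Y-linked level as a covariate 365 genes passed. That level was 0.879 to 1.07 in 6w BM and 0.0041 or less in 8w BM, so the covariate raised the standard errors 2.28-fold in the median, and fewer calls do not show an effect of sex. It ended the calls of Cxcl2 (log2 change -3.37, standard error 0.53, and -3.14, 1.22 with it; adjusted p = 0.212), C1qa (1.76, 0.29 and 1.94, 0.68; 0.151) and Mpeg1 (1.17, 0.19 and 1.23, 0.44; 0.167), whose changes stayed near the same size. The changes of Myl10 (2.42, 0.41 and 0.49, 0.83; 0.903) and Xist (6.58, 0.9 and 0.31, 1.43; 0.984) shrank. The monocyte and macrophage list kept its call (adjusted p = 8.55e-07), as did the immediate-early (8.05e-10), heat shock (8.43e-08), quiescence (0.000343), p53 target (0.0187) and Y-linked (2.36e-08) lists. The covariate was itself the mean level of Y-linked genes, yet the Y-linked list kept a median log2 change of -0.98. The covariate thus did not remove the Y-linked difference, and a kept call does not show that a list is independent of sex. Lost with the covariate were the camera calls of MHC class II (adjusted p = 0.68), megakaryocyte genes (0.103) and chromatin remodellers and H3K4 or H3K27 enzymes (0.103). So were those of the interferon response (0.966) and oxidative phosphorylation (0.949).

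**Figure D4:**
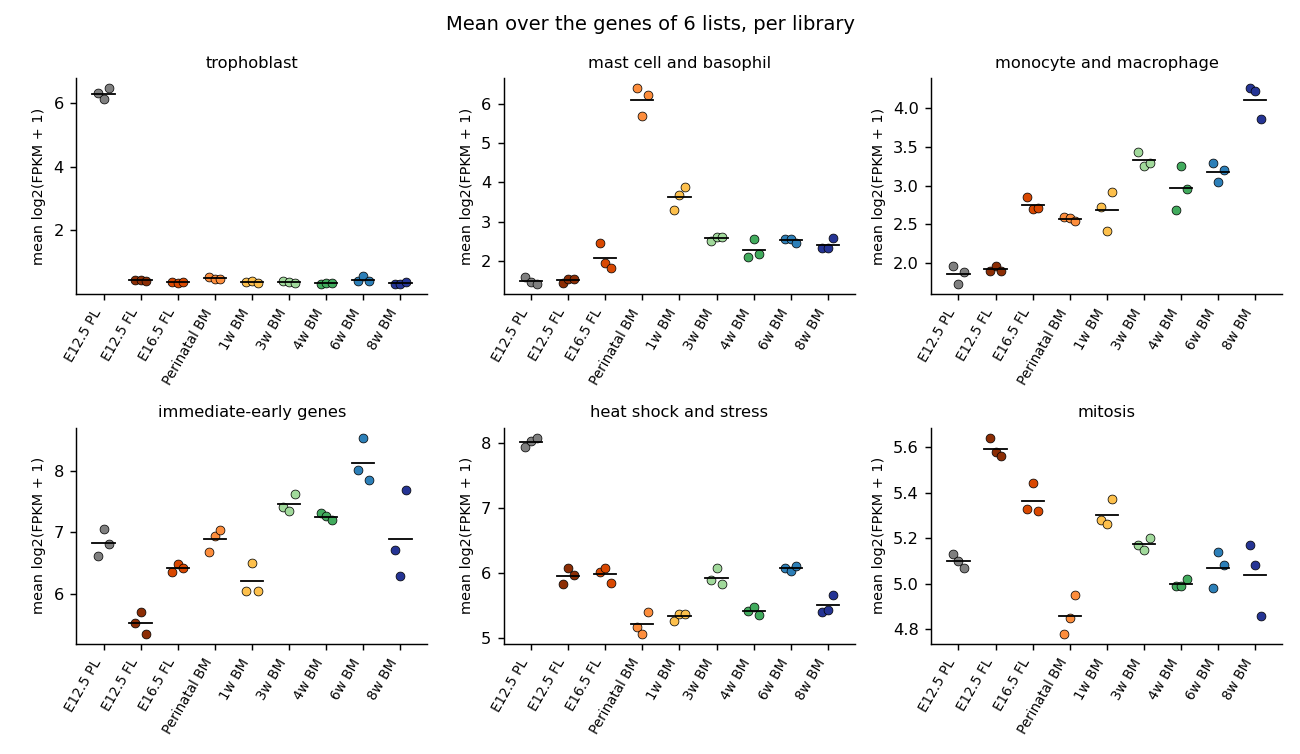
Mean log2(FPKM + 1) over the genes of 6 lists in each of the 27 libraries, with horizontal lines at the group means. The vertical axes differ between panels and do not start at 0.

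**Figure D5:**
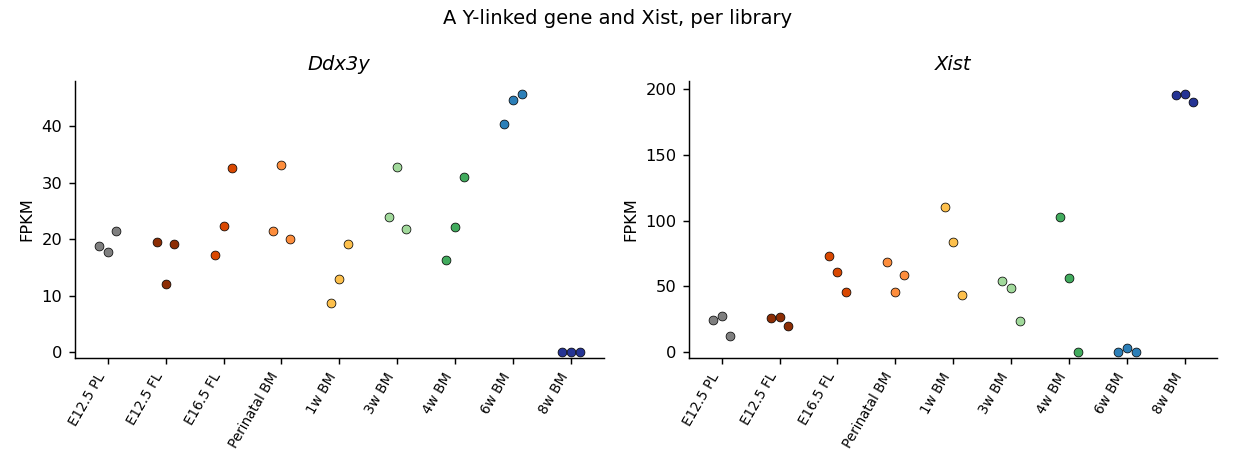
FPKM of Ddx3y and Xist in each library, by group. Xist was at 190 to 196 in the 8w BM libraries and at most 2.96 in the 6w BM libraries.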

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

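The fits without E12.5 PL, with the Y-linked level as a covariate, and with 1w BM or 6w BM in place of another group were chosen after seeing the data. Of 1017 gene results, 987 kept their direction and side of the threshold with a pseudocount of 0.1, 965 without a filter, 1014 with median-of-ratios scaling, 1009 with a replicate block, 755 with only the 6 libraries compared and 916 with the Y-linked covariate, as did 942 of 942 with the filter at 5 and 869 of 869 without E12.5 PL. No gene result reversed under these alternatives. Of 131 list calls, 129, 130, 131, 131, 120 and 119 held under the same 6 alternatives, 121 with the filter at 5, 115 of 119 without E12.5 PL and 17 with an estimated correlation. With each library left out in turn, 5471 of 6102 gene results held and 631 lost their call. Of 786 list results 723 held, 61 lost their call and 2 reversed. With only the 6 libraries in the fit the counts of changed genes were 2145 for Perinatal BM against E16.5 FL, 899 for 1w BM against Perinatal BM, 104 for 4w BM against 3w BM, 10 for 6w BM against 4w BM and 6 for 8w BM against 6w BM. They were 9566 for E12.5 FL against E12.5 PL and 5177 for E16.5 FL against E12.5 FL (9911 and 4620 in the main fit). This fit has fewer libraries to estimate the spread and takes no spread from the other groups. The lowest correlation within a group was 0.994 in E12.5 FL, 0.987 in 6w BM and 0.981 in Perinatal BM. A spread pooled over all groups may thus be too small for some of them, and their p-values with it. With the Y-linked covariate the counts of changed genes were 2921 for 8w BM against Perinatal BM and 365 for 8w BM against 6w BM, and the covariate raised the standard errors of these comparisons 1.6-fold and 2.28-fold in the median. With 1w BM in place of Perinatal BM the count was 2490 for 8w BM against Perinatal BM (1879 shared in the same direction and 15 opposite) and 2967 for Perinatal BM against E16.5 FL (1658 and 32). With 6w BM in place of 8w BM it was 5099 against Perinatal BM (3483 and 58) and 4620 against E16.5 FL (3474 and 44). Leaving out 1 library gave 9444 to 9701 genes for E12.5 FL against E12.5 PL, 3583 to 4016 for E16.5 FL against E12.5 FL, 2945 to 3841 for Perinatal BM against E16.5 FL, 4299 to 4687 for 8w BM against Perinatal BM and 4414 to 4916 for 8w BM against E16.5 FL. For the steps the ranges were 1462 to 2423 (1w BM), 738 to 988 (3w BM), 363 to 1644 (4w BM), 237 to 588 (6w BM) and 478 to 1076 (8w BM). The direction of the list test reversed for the interferon response in 1w BM against Perinatal BM without Perinatal BM 3 (median log2 change -0.02, adjusted p = 0.992, with medians from -0.4 to -0.02 over the left-out libraries). It also reversed for oxidative phosphorylation in 6w BM against 4w BM without 6w BM 2 (0.01, adjusted p = 0.945, with medians from -0.2 to 0.01). With the Y-linked covariate the interferon response (-0.08, adjusted p = 0.966) and oxidative phosphorylation (-0.02, adjusted p = 0.949) reversed in 8w BM against 6w BM, and the cause was not tested. Depth limits the values of genes near 0.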

Other observations

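The tests of pan-leukocyte genes, of scaling, of mislabelled and exchanged libraries and of handling were chosen only after the results they bear on were seen. Over the 6 BM ages, 304 of 13350 genes had group means of log2(FPKM + 1) that rose (173) or fell (131) at every step. Among those that rose from Perinatal BM to 8w BM were Cdkn2c, a cell cycle inhibitor, from 1.71 to 15.1 FPKM, Muc13, a mucin, from 25.2 to 118, Vwf, the von Willebrand factor, from 2.23 to 8.27, and H2-D1 from 221 to 558. Dlk1 fell from 14.5 to 0.336, Cnn3, a calponin, from 76.7 to 20.4, Ccnd1, a G1 cyclin, from 23.8 to 8.2, and Dnmt3b from 65.2 to 27.3. These genes were chosen after their values were seen.

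The chemokine genes Ccl3 and Ccl4, chosen after their values were seen, followed no such order. Ccl3 was at 261 ± 41.2 in E12.5 FL, 38.1 ± 3.87 in 1w BM, 238 ± 16.2 in 6w BM and 120 ± 34.5 in 8w BM, and Ccl4 at 132 ± 31.4, 13.6 ± 3.53, 155 ± 11.1 and 62.5 ± 39.3. S100a8 was at 451 ± 140 in 1w BM and 3.76 ± 1.04 in 4w BM. Rps27 ranged from 11.4 to 3770 and its near-identical copy Rps27rt from 205 to 4150 over the libraries, while their sum ranged from 2170 to 4160, so each value alone is uncertain.

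For the ordered means, a change with age was set against the other orders of the 6 groups. The order of age ranked 1 of 360 orders by the number of genes, with 304 genes against 268 in the highest other order, which exchanged 6w BM and 8w BM. A median of 24 genes followed the other orders. An ordered change with age may account for these genes, and batches that follow age stay open.

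Trophoblast, stromal and endothelial genes were higher in E12.5 PL than in E12.5 FL. Scaling or depth is argued against, since the trophoblast list lay -5.8 from all genes (medians of -5.86 and -0.06 on the log2 scale, FL minus PL). Cells of other types in the PL libraries are a candidate explanation, since 20 of 20 pan-leukocyte genes were lower in PL, with a median log2 ratio of -2.49. All 20 trophoblast genes reached an FPKM of 1 in PL and 2 in FL (3 are in another list), as did 20 and 5 of 20 stromal genes (1 in another list) and 22 and 14 of 22 endothelial genes (4 in another list), with Col4a1 at 3830 and Krt8 at 872 in PL. Most trophoblast genes thus passed the filter through PL, which partly fixes their shared direction. No purification gate is stated, and a difference in the HSPCs themselves was not tested.

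Mast cell genes were higher in Perinatal BM than in E16.5 FL, with Tpsb2 at 849 and Cma1 at 773. Of the 16 list genes, 2 are in another list, and 10 reached an FPKM of 1 in E16.5 FL and 10 in 8w BM. An exchange of 1 or 2 of these libraries with another group is argued against, since the lowest mean of the list among them (5.69) lay 1.8 above the highest of the other 24 libraries (3.89), where the widest range within a group was 0.7. Wrong labels of all 3 libraries, or a sample from outside the series, stay open, as 6 of 10 fetal genes had Perinatal BM means between E16.5 FL and 1w BM. Among the 6 were Igf2bp2 (38.8, 19.6 and 9.49 in E16.5 FL, Perinatal BM and 1w BM) and Hmga2 (187, 115 and 80.9). Lin28a, Igf2bp3, Mycn and Plag1 did not lie between. Lin28a, and Sox17 among the 6, were below a mean FPKM of 1 in these groups. On component 1 without E12.5 PL, the Perinatal BM libraries (-14.2 to -8.3) lay between E16.5 FL (-27.6 to -26.5) and 1w BM (-3.6 to -1.1). That is the order of the labels. A mast-like population of varying share also stays open. The 49 other genes at least 4-fold higher included further mast genes such as Mcpt1. Their median log2 ratio of library 2 to libraries 1 and 3 was -0.67, against -0.94 for the list, and 42 of them were lower in library 2. Of 10000 random sets of matched expression 0 were as low (median 0.01, 2.5th percentile -0.08). The prediction set before the test was thus met. However, the random sets were matched on mean expression only, while the 49 genes were picked from these same libraries and include mast genes. Such genes were likely to follow the list, so the share of random sets does not measure chance. Cpa3, Tpsb2, Cma1 and Mcpt4 were all lowest in library 2. However, only 30 of the 49 lay within 0.5 of the list. The MHC class II genes Cd74 and H2-Aa were lowest in library 1, and Prg2, Epx and Ms4a2 in library 3. Whether these genes belong to such a population was not tested, nor was a change within the HSPCs.

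Many genes changed from 6w BM to 8w BM, groups that also differed in Y-linked genes. A sex difference shared by all ages as the whole cause is argued against, since within 6 other groups (18 libraries) the changed genes had a slope on the Y-linked level of -0.21 (95% interval -0.44 to 0.02), where 0.68 was needed. The wording of that explanation was narrowed after the result was seen, and a sex difference arising later may remain. Handling of the 6w BM libraries stays open, since the immediate-early list had a median log2 change of -0.35 from 4w BM to 8w BM, with 15 of 22 genes lower. A change with age was not tested apart from these.

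For each comparison the 6 libraries allow 10 splits, and 1 split, the real one, gave as many changed genes, so the share is never under 0.1 and the splits are too few. Every other split mixes libraries of both groups, which puts a difference between the groups into the spread. Low counts in the other splits thus follow wherever the groups differ, and do not measure what chance gives. The real counts and the highest of the other splits were 9911 and 2 for E12.5 FL against E12.5 PL, 4620 and 1 for E16.5 FL against E12.5 FL, 3786 and 49 for Perinatal BM against E16.5 FL, 5050 and 1 for 8w BM against Perinatal BM, and 5362 and 0 for 8w BM against E16.5 FL. For the steps they were 2345 and 1 (1w BM), 1394 and 0 (3w BM), 1239 and 1 (4w BM), 526 and 3 (6w BM) and 1092 and 3 (8w BM).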
